A study of Oryza sativa Japonica Group with 8 samples.

How the data were processed

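Messenger RNA of young rice panicles was measured in 3 wild type and 3 dcl3b knockdown libraries and small RNA in 1 library of each genotype. Per the labels' protocols, RNA was extracted with Trizol and freed of DNA, and the libraries were made with stranded mRNA and small RNA kits from Illumina. Per the submitters' processing notes, TopHat2 2.1.0, Bowtie 1.1.2 and edgeR were used, without a statement of which step each served. The genome build, the annotation release, the filters and the handling of reads with several matches are not given in the sources used here.

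The authors deposited lists of genes called higher or lower, with FPKM values of each library per the file headers, rounded to 2 decimals. The authors also deposited a log2 fold change of knockdown over wild type, a p-value and an adjusted p-value (FDR) for each gene, and a description. The base of the fold change is not written in the files. It was checked against the FPKM values: over 369 genes above 1 FPKM in both genotypes the deposited log2 fold change and the log2 ratio of mean FPKM differed by a median of 0.00318 and at most 0.0326. The small RNA files deposited by the authors list windows of 500 bases for 21-nt and 24-nt siRNA, with a signal per library in RPTM (taken as reads per 10000000 library reads), a fold ratio, a p-value and an adjusted p-value. The deposited ratio, p-values and FDR of windows were not used, since each genotype had 1 small RNA library.

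Only genes and windows called by the authors were held, so no new test across the genome was made and unlisted genes were not analysed here. Fold changes and adjusted p-values of genes are those of the authors' deposited table. They scale FPKM by the authors' normalization, which was not varied here. Gene descriptions came from the files. None of the listed locus IDs matched the gene table at hand (0 matches), so genes are named by locus ID and description.

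Gene lists were fixed before the data were examined: 7 lists of locus IDs, written from general knowledge of rice genes and not checked against a gene table, and 25 lists of keywords matched to the descriptions without regard to case. Each list with at least 5 listed members (20 of 32) was tested by Fisher's exact test, two-sided, of genes that rose against genes that fell, with Benjamini-Hochberg adjustment over the tested lists in SciPy 1.17.1. The test asks whether a list leaned one way among the changed genes, not whether it changed more often than other genes. It takes genes as independent, while genes of a list can move together between libraries, so its p-values can be too small. Genes named in the text were the members of the small RNA machinery list, up to 4 genes per list with the largest absolute log2 fold change, and the 5 described genes outside transposons with the largest change in each direction. The windows named were the 5 with the largest ratio in each direction and size class among those above the median by the higher library, with windows that had no read in a library ranked by the ratio to 3 reads. Listed members of the anther and tapetum list beyond those, the 3 adjoining windows of the pectinesterase gene, the 24-nt windows named as most abundant without a knockdown read and the genes in both kinds of table were named after their values were seen.

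The listed genes were re-tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.5), with Benjamini-Hochberg adjustment over the listed genes. Fold changes on that scale understate the change of low genes. The re-test served only to compare settings: it runs on genes already selected on the same values. It was tested on simulated data for knockdown against wild type with 1174 genes, of which 200 were changed: it recovered 71% of those changed by 1 on the log2 scale and 96% of those changed by 2, with calls in 0.821% of unchanged genes. These rates do not carry over to the real table, in which every gene had already been called changed. Fits with a library left out were not simulated. The settings of the re-test were pseudocounts of 0.1 and 1, a replicate block, the lowest 25% of genes by mean left out, and each library left out in turn. Gene lists with a library left out were made of the genes past the re-test and set against those past it with all libraries. Stricter limits were an absolute log2 fold change of at least 2 and an adjusted p of at most 0.01.

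All 121 nonzero window values of the wild type library and all 100 of the knockdown library were whole multiples of a single step, 1.24 and 1.36 RPTM, to within 0.01 RPTM. The steps correspond to 8037518 and 7358371 reads per library, from which read counts per window were taken. Ratios have exact (Clopper-Pearson) 95% binomial intervals of these reads. Where a library had no read, the ratio was computed against a floor of 3 reads, about the one-sided 95% upper limit of a count of 0. Such a ratio is not a lower bound, since it leaves out the counting error of the other library. Intervals and floors cover counting error only, since the reads carry no molecular identifiers. Tables were handled with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.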

Results

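Young panicles of field-grown japonica rice, collected before heading, were profiled in wild type plants and in a line with reduced expression of OsDCL3b, a Dicer-like endonuclease that cuts double-stranded RNA into small interfering RNAs (siRNAs). Messenger RNA was sequenced with a stranded kit in 3 wild type and 3 knockdown libraries. Small RNA was sequenced in 1 library of each genotype. For mRNA, the files held the 1174 genes that the authors called changed, with the depth- and length-scaled level (FPKM) of each library, and genes outside those lists were not analysed here. For small RNA, the files held 500-base windows called changed for 21-nt and for 24-nt siRNA, in reads per 10000000 library reads (RPTM). The small RNA values corresponded to library totals of 8037518 reads in wild type and 7358371 reads in the knockdown, and the depth of the mRNA libraries is unknown.

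The gene targeted by the knockdown, LOC_Os10g34430, described in the files as Dicer, was measured first. Its level was 0.97, 0.98 and 0.88 FPKM in the wild type libraries and 0.39, 0.50 and 0.44 FPKM in the knockdown libraries, or 0.943 ± 0.0551 against 0.443 ± 0.0551 FPKM (SD, n = 3 each). The authors' deposited table gave it a log2 fold change of -1.09 with an adjusted p of 5.49e-07. Of 22 genes of the small RNA machinery fixed as a list before the data were examined, which comprise Dicer-like proteins, Argonautes, RNA-dependent RNA polymerases and their partners, this gene was the 1 member among the listed genes. The other 21 members were in neither list of changed genes. The locus IDs of the fixed lists were not checked against a gene table, and a wrong ID also counts as not listed.

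The first comparison asked which transcripts of the young panicle differed between the knockdown and wild type. The knockdown had 644 genes at higher and 530 genes at lower levels, and the directions differed in starting level. Genes that rose were mostly near silence in wild type, with a median of 0.108 FPKM there and 0.952 FPKM in the knockdown. Genes that fell came from a median of 1.83 FPKM down to 0.703 FPKM. Among the genes that rose, 133 were listed at 0 FPKM in all 3 wild type libraries, whereas 2 of the genes that fell were listed at 0 in all 3 knockdown libraries.

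The largest increases among described genes outside transposons included LOC_Os12g29690 and LOC_Os12g29710, both NBS-LRR disease resistance proteins, a class of intracellular immune receptors. LOC_Os12g29690 was listed at 0 in every wild type library and at 0.90, 0.91 and 0.89 FPKM in the knockdown. LOC_Os12g29710 was listed at 0 in wild type and at 0.34, 0.28 and 0.46 FPKM in the knockdown. LOC_Os01g18780, described as a fibroin heavy chain precursor, was also listed at 0 in wild type, and reached 0.64, 1.11 and 0.63 FPKM. LOC_Os01g35330, described as a circumsporozoite protein precursor, rose from 0.193 ± 0.106 to 66.8 ± 5.09 FPKM (SD, n = 3), and LOC_Os06g19360, described as a cadmium tolerance factor, from 0.00667 ± 0.0115 to 1.93 ± 0.348 FPKM. The deepest fall among such genes, a log2 fold change of -5.57 in the authors' deposited table, was in LOC_Os02g15710. This plastocyanin-like protein was at 0.62, 0.46 and 0.15 FPKM in wild type and listed at 0 in the knockdown. Next came a cytochrome P450 gene, LOC_Os02g36070 (-5.39), which fell from 4.71 ± 1.49 to 0.103 ± 0.112 FPKM. The PHD finger gene LOC_Os01g06540 (-4.91) was at 0.10, 0.11 and 0.22 FPKM in wild type and listed at 0 in the knockdown. The mitogen-activated protein kinase gene LOC_Os10g06930 fell from 0.370 ± 0.161 to 0.0133 ± 0.0231 FPKM, and LOC_Os04g21705, with a PB1 domain, from 0.230 ± 0.0889 to 0.01 ± 0.0173 FPKM.

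In the authors' deposited table every listed gene had an absolute log2 fold change of at least 1 and an adjusted p of at most 0.05. For the genes above 0 FPKM in both genotypes, the median log2 fold change in the authors' deposited table was 2.04 over 511 genes that rose and -1.44 over 528 genes that fell. The 3 knockdown values all lay above the 3 wild type values for 545 (84.6%) of the genes that rose and all lay below them for 472 (89.1%) of those that fell, where chance alone gives 10% for 3 against 3. These genes were selected on the same values. Replicate 2 of both genotypes stood nearest to the other genotype in many genes that fell: wild type replicate 2 was the lowest of wild type in 295 and knockdown replicate 2 the highest of the knockdown in 360 of the 530. Genes that rose were affected too. Those with all knockdown values above all wild type values went from 545 to 623 without knockdown replicate 2 and to 610 without wild type replicate 2. Leaving out any other library gave 547 to 557. For genes that fell the counts were 524 and 526, against 472 to 476 without any other library. An exact permutation test of 3 against 3 cannot go below p = 0.10 for any single gene. The labels do not say whether the libraries came from separate plants, so the p-values measure the spread between these samples, which may be technical.

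**Figure D1:**
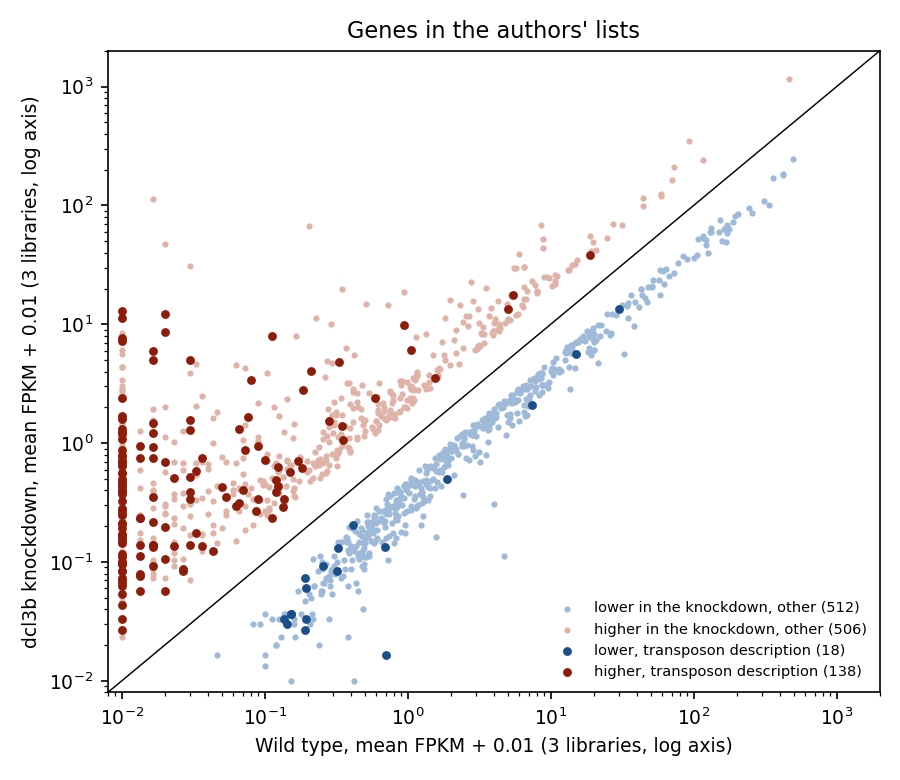
Mean FPKM of each listed gene in wild type (x axis) and in the knockdown (y axis), over 3 libraries each, on log axes after adding 0.01; each point is a gene and the line marks equal levels. The 138 genes with a transposon description that rose lie toward the left edge, where wild type values are at or near 0, and 18 such genes fell.

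Among the 20 gene lists tested, transposon-related genes made up the largest group of the transcripts that rose; 179 genes that rose (27.8%) had no functional description. They numbered 138 of 644 genes that rose (21.4%) and 18 of 530 genes that fell (3.40%). This was the difference with the smallest adjusted p of the tested lists (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 1.42e-20). The test did not adjust for the level in wild type. Transposon genes that rose had a median of 0.00667 FPKM there, and genes so low can be called higher but hardly lower. Leaving out the genes listed at 0 in wild type does not remove this limit. Among the members that rose, 104 were described as retrotransposon proteins, 12 belonged to the CACTA class and 9 to the Pong class of DNA transposons, and 2 to the Mutator class. Of the retrotransposon descriptions, 6 named Ty1-copia, 3 named LINE and 2 named Ty3-gypsy elements. No listed gene of the Pong, Ty1-copia, LINE and Mutator classes fell, while 4 CACTA and 2 Ty3-gypsy genes did.

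The 4 transposon genes with the largest changes were listed at 0 FPKM in every wild type library. LOC_Os03g26010, a retrotransposon protein, stood at 13.8, 13.1 and 11.9 FPKM in the knockdown, and its neighbour in locus number LOC_Os03g26020 at 7.64, 7.31 and 8.08 FPKM. LOC_Os07g47800, an unclassified transposon protein, stood at 10.5, 11.8 and 11.6 FPKM, and the LINE gene LOC_Os04g13000 at 7.09, 8.19 and 6.59 FPKM. Of the 138 genes, 58 were listed at 0 in all wild type libraries, and 135 had all 3 knockdown values above all wild type values. Without the genes listed at 0, the median log2 fold change in the authors' deposited table was 3.64 over 80 transposon genes and 1.87 over the other 431 genes that rose. These medians do not show that transposon genes rose more strongly. With the genes listed at 0, the median wild type level was 0.00667 FPKM for transposon genes that rose and 0.108 FPKM for all genes that rose. A gene near the floor needs a larger fold to be called. Transposon copies resemble each other, so how reads were shared between copies affects these levels and is not given in the sources used here.

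Of 22 genes fixed as an anther and tapetum list before the data were examined, 11 fell, 1 rose and 10 were not listed as changed (two-sided Fisher's exact test of higher against lower, adjusted p = 0.00886). Here and for the other lists, the test counts genes that move together between libraries as independent. The tapetum is the innermost cell layer of the anther wall, which feeds the developing pollen and supplies its wall. The cytochrome P450 gene LOC_Os08g03682 fell from 256 ± 13.6 to 85.6 ± 39.9 FPKM (SD, n = 3), and a further cytochrome P450 gene, LOC_Os03g07250, from 423 ± 19.3 to 180.4 ± 69.2 FPKM. The stilbene synthase gene LOC_Os10g34360 fell from 491 ± 62.6 to 244 ± 82.7 FPKM. LOC_Os07g22850, described as a chalcone and stilbene synthase, fell from 175 ± 3.82 to 63.7 ± 33.6 FPKM, and the AMP-binding enzyme gene LOC_Os04g24530 from 358 ± 23.2 to 171 ± 65.8 FPKM. LOC_Os03g07140, described as a male sterility protein, fell from 131 ± 20.7 to 59.5 ± 23.8 FPKM. Regulators on the list fell too, among them the PHD-finger gene LOC_Os09g27620 (9.51 ± 1.5 to 2.89 ± 1.70 FPKM), the MYB gene LOC_Os04g39470 (9.97 ± 0.898 to 4.06 ± 1.54 FPKM) and the helix-loop-helix gene LOC_Os01g18870 (8.93 ± 2.72 to 4.40 ± 1.38 FPKM).

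The largest fall of the list was that of the aspartic proteinase gene LOC_Os04g37570, with 38.2 ± 5.92 against 9.74 ± 5.66 FPKM and a log2 fold change of -1.97 in the authors' deposited table. Across the 11 genes the log2 fold changes in the authors' deposited table ran from -1.97 to -1.01, with adjusted p-values up to 0.00197. All 11 had the 3 knockdown values below the 3 wild type values, and in all 11 knockdown replicate 2 was the highest of the knockdown libraries. Adjusted over the list alone, with the unlisted members set to 1, the authors' p-values of all 12 listed members passed. This could hardly fail and adds no support, since the 12 were listed for passing the authors' threshold. In a re-test with limma, which all 11 passed with every library (adjusted p = 0.00184 for the list over the genes that passed), 6 of the 11 passed without wild type replicate 1, without wild type replicate 3 and without knockdown replicate 3, with adjusted p = 0.0196, 0.0314 and 0.0190 for the list. Without wild type replicate 2, 7 of the 11 passed and the list's adjusted p was 0.0674. No member had an absolute log2 fold change of at least 2 in the authors' deposited table.

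The member that rose, the anther-specific LEM1 family gene LOC_Os01g70440, varied widely, at 97.3, 157 and 22.1 FPKM in wild type and 331, 112 and 611 FPKM in the knockdown. It belonged to a set of 9 genes, 3 from the keyword list of pollen and anther proteins and 6 from the lipid transfer list, that were listed as higher and above 0 in wild type. Among them were the LEM1 family gene LOC_Os02g32080, at 5.71 ± 4.41 against 29.7 ± 23.4 FPKM (SD, n = 3), and the lipid transfer protein genes LOC_Os04g33930, at 8.81 ± 6.51 against 43.8 ± 32.4 FPKM, and LOC_Os12g02320, at 2.54 ± 0.944 against 11.6 ± 6.72 FPKM. In all 9, knockdown replicate 2 was the lowest of the knockdown libraries, and 2 of the 9 had knockdown values that all lay above the wild type values. The keyword list of pollen and anther proteins held 3 genes that rose and 4 that fell (adjusted p = 0.786). The lipid transfer list held 7 that rose and 14 that fell (adjusted p = 0.101). Over the genes past the limma re-test its adjusted p was 0.0490 with all libraries, a call that ended when any one library was left out. In 13 of the 14 that fell knockdown replicate 2 was the highest of the knockdown. In 7 of the 14 all knockdown values lay below all wild type values. The lists of storage proteins and of protease inhibitors, each with 8 that rose and 14 that fell (adjusted p = 0.124), were the same 22 genes, 21 of them lipid transfer proteins.

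**Figure D2:**
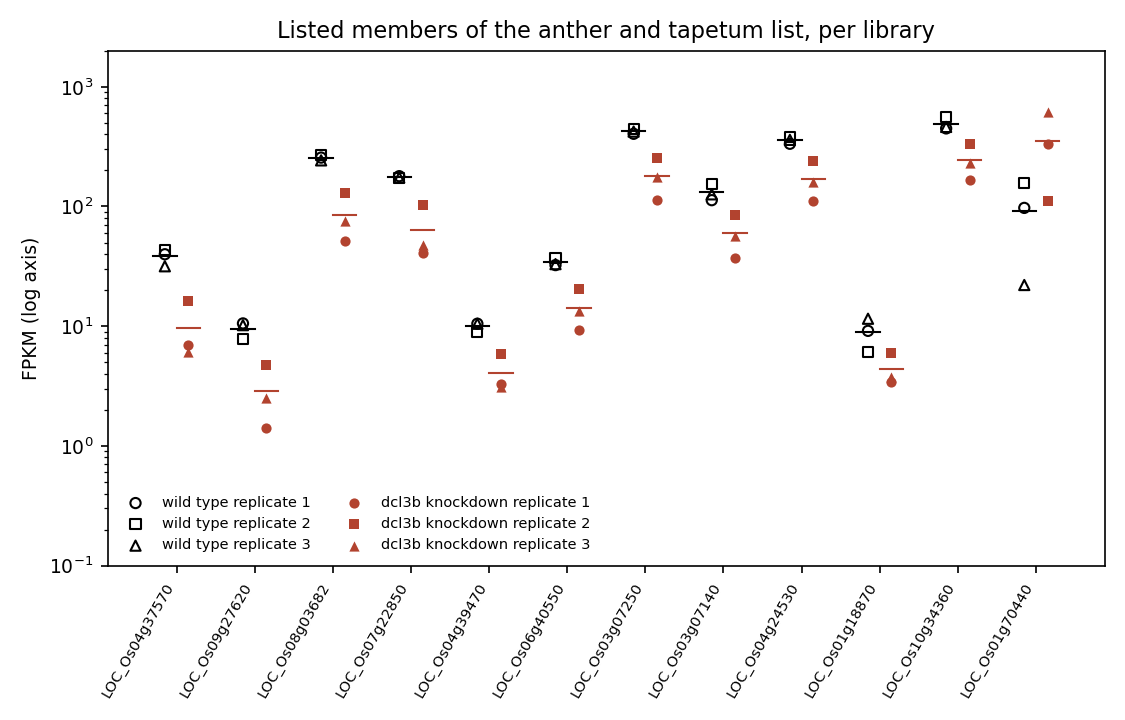
FPKM (log axis) of the 12 listed members of the anther and tapetum list in each of the 6 libraries; open symbols are wild type, filled symbols the knockdown, symbol shapes the replicate numbers and short lines the means. In 11 genes every knockdown value lies below every wild type value, and in LOC_Os01g70440 the values overlap.

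All 9 listed genes with a heat shock, HSP20, DnaJ or DnaK description fell and none rose (two-sided Fisher's exact test, adjusted p = 0.00500); 2 of them had an absolute log2 fold change of at least 2 in the authors' deposited table, too few for the test. Wild type replicate 2 was the lowest of wild type in all 9, and all 9 had the 3 knockdown values below the 3 wild type values. The small heat shock protein gene LOC_Os01g08860 fell from 57.7 ± 14.3 to 17.5 ± 4.61 FPKM (SD, n = 3), the mitochondrial heat shock protein gene LOC_Os02g52150 from 6.81 ± 2.07 to 1.73 ± 0.373 FPKM, and the DnaJ genes LOC_Os12g44260 and LOC_Os06g09560 from 0.947 ± 0.297 to 0.197 ± 0.0751 FPKM and from 1.17 ± 0.140 to 0.290 ± 0.157 FPKM. Of 9 heat shock genes fixed by locus, 4 fell and 5 were not listed as changed. Of these 4, 3 were already among the 9 genes found by description. The other was the heat shock transcription factor gene LOC_Os03g53340, from 1.58 ± 0.476 to 0.153 ± 0.133 FPKM. That list had too few listed members to be tested.

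F-box genes, whose products select proteins for ubiquitin-dependent degradation, numbered 26 among the genes that fell and 8 among those that rose (adjusted p = 0.00314). In 17 of the 26 knockdown replicate 2 was the highest of the knockdown. LOC_Os06g35080 fell from 0.207 ± 0.0802 to 0.0233 ± 0.0404 FPKM (SD, n = 3). Against the direction of most of the list, LOC_Os10g41838 rose from 0.950 ± 0.0693 to 9.63 ± 0.816 FPKM and LOC_Os02g57890 from 0.05 ± 0.0436 to 0.393 ± 0.236 FPKM, and LOC_Os03g47420 was listed at 0 in wild type and at 0.15, 0.44 and 0.07 FPKM in the knockdown. Restricted to genes with an adjusted p of at most 0.01, the list held 7 that rose and 8 that fell and the difference ended (adjusted p = 0.534). Past the limma re-test with all libraries it held 8 that rose and 26 that fell (Fisher's exact test, adjusted p = 0.00355). Without knockdown replicate 1 it held 6 and 15, with the highest adjusted p of the fits with a library left out (0.0417).

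Of the listed cell wall genes 16 fell and 5 rose (adjusted p = 0.0257). In 15 of the 16 wild type replicate 2 was the lowest of wild type and in 11 knockdown replicate 2 the highest of the knockdown, and 15 had all knockdown values below all wild type values. The pectinesterase gene LOC_Os03g19610 fell from 0.273 ± 0.0709 to 0.0667 ± 0.0306 FPKM (SD, n = 3), the fasciclin-like arabinogalactan protein gene LOC_Os06g44660 from 5.34 ± 2.26 to 1.42 ± 0.828 FPKM and the endoglucanase gene LOC_Os05g12150 from 0.567 ± 0.153 to 0.167 ± 0.0907 FPKM. The cellulose synthase-like gene LOC_Os07g36690 rose from 0.02 ± 0.01 to 0.233 ± 0.283 FPKM. Without the genes listed at 0 in wild type, the list's adjusted p was 0.0988. With an absolute log2 fold change of at least 2 in the authors' deposited table it kept 1 gene on each side.

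Histone genes fell in 6 of 6 listed cases (adjusted p = 0.0278), among them LOC_Os08g38300, from 50.8 ± 22.8 to 20.99 ± 7.45 FPKM (SD, n = 3), LOC_Os05g02300, from 22.6 ± 9.54 to 9.77 ± 3.94 FPKM, and the H3 genes LOC_Os06g06510, from 15.6 ± 6.93 to 7.12 ± 2.49 FPKM, and LOC_Os04g34240, from 3.84 ± 2.0 to 1.57 ± 0.398 FPKM. In all 6 the libraries overlapped: wild type replicate 2, the lowest of wild type, lay below knockdown replicate 2, the highest of the knockdown, with LOC_Os08g38300 at 26.7 and 29.2 FPKM. The median log2 difference was -1.40 for wild type replicate 2 minus 3 and -0.76 for knockdown replicate 3 minus 2. All 5 listed MYB and all 5 listed NAC transcription factor genes fell (adjusted p = 0.0464 for each list). The MYB genes include LOC_Os04g39470, also counted in the anther and tapetum list. All knockdown values lay below all wild type values in 3 of the 5 MYB genes and in all 5 NAC genes. Wild type replicate 2 was the lowest of wild type in 4 MYB genes and 1 NAC gene, and knockdown replicate 2 the highest of the knockdown in 5 and 3. The MYB genes included LOC_Os03g18480, from 8.27 ± 2.83 to 2.54 ± 1.49 FPKM, and the NAC genes LOC_Os12g23090, from 0.570 ± 0.0624 to 0.133 ± 0.146 FPKM, and LOC_Os05g34310, from 0.260 ± 0.0557 to 0.0633 ± 0.0404 FPKM. Of the histone genes 3 passed the limma re-test with all libraries, too few for the list's test, 6 without wild type replicate 2, 5 without knockdown replicate 2 and none without any other library. Of the MYB genes 4 passed it with all libraries, again too few. Over the genes past it the NAC list had adjusted p = 0.0490 with all libraries, 0.0463 without knockdown replicate 2 and 0.0596 without wild type replicate 2, with under 5 members without any other library. With an absolute log2 fold change of at least 2 in the authors' deposited table the lists kept 3 NAC genes and no histone or MYB gene. Without the genes listed at 0 in wild type the adjusted p was 0.0988 for histones and 0.124 for the MYB and the NAC list.

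Several lists had members on both sides without a difference past the threshold. Cytochrome P450 genes numbered 13 that rose and 4 that fell (adjusted p = 0.124; over the genes past the limma re-test 0.121 with all libraries and 0.0262 without wild type replicate 1), with LOC_Os06g19070 at 0.467 ± 0.172 FPKM in wild type and 3.10 ± 0.644 FPKM in the knockdown (SD, n = 3). Peroxidase genes numbered 9 that rose and 2 that fell (adjusted p = 0.166), the most abundant named one being LOC_Os05g41990, at 72.3 ± 27.9 and 211.6 ± 76.5 FPKM. In the limma re-test 8 peroxidase genes passed as higher with all libraries, and 8 without replicate 2 of either genotype. Without wild type replicate 3, knockdown replicate 1 or knockdown replicate 3, 3 passed. Protein kinase genes numbered 26 and 16 (adjusted p = 0.538), with LOC_Os08g14950 rising from 0.0167 ± 0.0115 to 1.26 ± 0.0400 FPKM. Transporter genes numbered 19 and 15 (adjusted p = 1), zinc finger genes 4 and 10 (adjusted p = 0.107), NBS-LRR and related resistance genes 6 and 3 (adjusted p = 0.617) and gibberellin genes 3 and 2 (adjusted p = 1). Of transporter genes 15 passed the limma re-test as higher with all libraries. Without wild type replicate 3, knockdown replicate 1 or knockdown replicate 3, 6 passed. Among auxin genes 1 rose and 6 fell (adjusted p = 0.101); the 6 were SAUR genes, including LOC_Os04g51890, from 1.42 ± 0.345 to 0.410 ± 0.236 FPKM. The gene that rose did not pass the limma re-test, over whose genes the auxin list had adjusted p = 0.0281 with all libraries, 0.116 without knockdown replicate 1 and 0.112 without knockdown replicate 2.

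Small lists were described without a test. Both listed MADS-box genes fell, among them LOC_Os02g49840, from 2.18 ± 0.332 to 0.890 ± 0.0173 FPKM (SD, n = 3), as did both WRKY genes, with LOC_Os05g49620 from 0.820 ± 0.132 to 0.150 ± 0.0656 FPKM, and the 3 AP2 domain genes, with LOC_Os04g18650 from 7.75 ± 0.554 to 2.72 ± 2.25 FPKM. The photosynthesis keywords matched 2 genes that rose and 2 that fell. These were the chlorophyll A-B binding protein gene LOC_Os01g64960, which rose, and genes described only as plastocyanin-like, which went both ways. Ribosomal protein descriptions were split 1 and 2, with LOC_Os01g67200 rising from 0.0200 ± 0.0173 to 3.88 ± 0.341 FPKM. None of 17 floral organ and MADS-box identity genes, 17 panicle architecture genes, 12 green tissue photosynthesis genes and 11 defence genes fixed by locus before the data were examined was among the authors' listed genes; these IDs were not checked, and the levels of the genes were not analysed here.

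**Figure D3:**
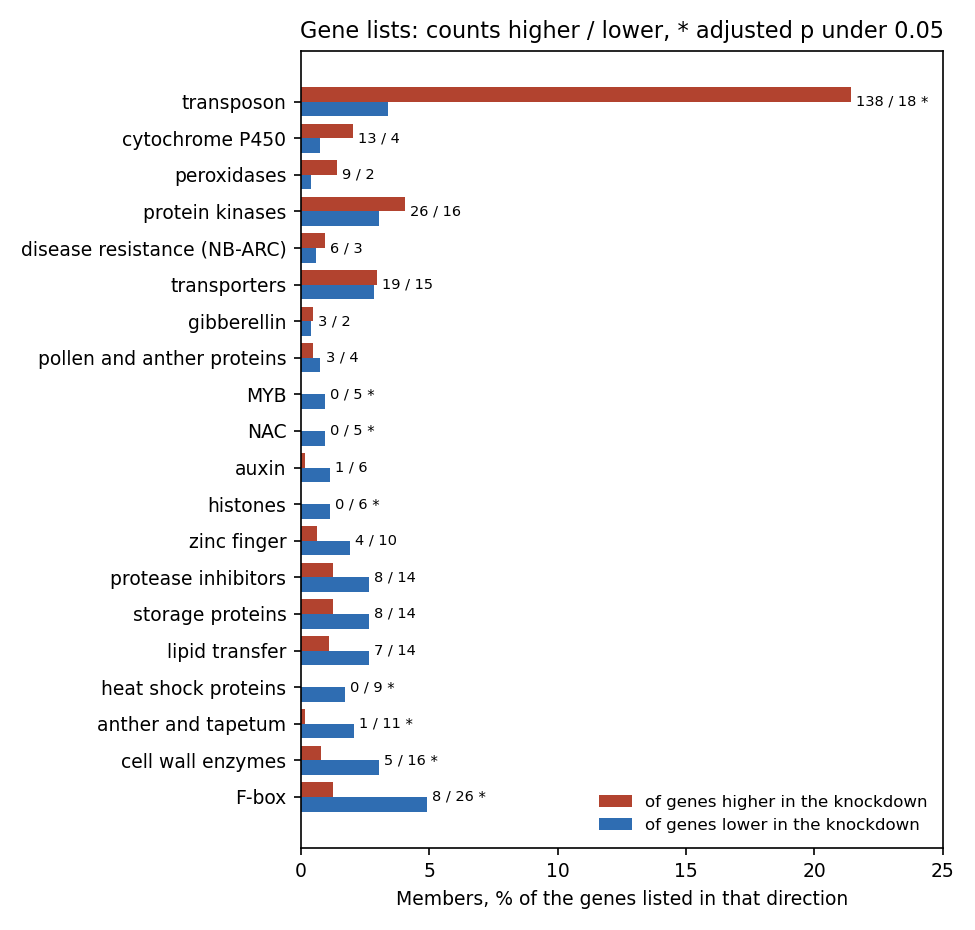
Share of the genes that rose (red bars) and of the genes that fell (blue bars) held by each of the 20 tested lists, in percent; numbers beside the bars are genes that rose and fell, and a star marks an adjusted p under 0.05 by Fisher's exact test. Transposon genes hold 21.4% of the genes that rose and 3.40% of those that fell, and the other 7 starred lists hold a larger share of the genes that fell.

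The small RNA comparison asked where siRNA abundance differed in the knockdown of a Dicer-like gene. For 24-nt siRNA, the size class that directs DNA methylation in plants, 87 of 113 listed windows (77.0%) were lower in the knockdown and 26 were higher. Windows that were higher all lay in annotated genes, 9 of them with a transposon description. Of the lower windows, 66 lay in genes, 15 of them with a transposon description, and 21 were intergenic. The median ratio was 8.22 among lower windows and 9.94 among higher windows with reads in both libraries. In 19 lower windows the knockdown library had no read, and in 3 higher windows the wild type library had none.

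Among 24-nt windows in the upper part of the list by value that had a read in both libraries, the largest losses lay in single genes and in intergenic sequence; coordinates are those of the authors' files, whose genome build is not given in the sources used here. On chromosome 2, from 2388000 to 2388499, in the sucrose-phosphatase gene LOC_Os02g05030, 24-nt siRNA went from 528 RPTM in wild type to 1.36 RPTM in the knockdown, or 424 reads and 1 read (ratio 388, 95% interval 69.3 to 15368, exact binomial). On chromosome 7, from 15912000 to 15912499, in LOC_Os07g27350, it went from 299 to 1.36 RPTM (ratio 219.6, 39.1 to 8714). The intergenic windows from 22406000 to 22406499 on chromosome 4 and from 1763500 to 1763999 on chromosome 11 went from 284 and 210.3 RPTM to 1.36 RPTM each. Of the windows without a knockdown read, the most abundant were one on chromosome 3 from 11693000 to 11693499, in the ELMO/CED-12 family gene LOC_Os03g20670, at 432 RPTM or 347 reads in wild type, and an intergenic one on chromosome 6 from 24700500 to 24700999, at 386 RPTM or 310 reads. Among the gains outside the Dicer gene was a window on chromosome 1 from 34353500 to 34353999, in LOC_Os01g59400. It had no wild type read and 213 RPTM in the knockdown. That is 57.2-fold higher than a floor of 3 reads, or 3.73 RPTM, in the wild type library. The exact interval, which also holds the counting error of the knockdown reads, starts lower, at 45.9. Windows in the deoxycytidylate deaminase gene LOC_Os01g55974 (chromosome 1, 32235500 to 32235999) and in LOC_Os09g18050 (chromosome 9, 11066000 to 11066499) had no wild type read. They had 198 and 155 RPTM in the knockdown, 53.2-fold and 41.5-fold higher than the same floor, with exact intervals that start at 42.7 and 33.2. The retrotransposon gene LOC_Os07g13190 (chromosome 7, 7563500 to 7563999) went from 3.73 to 135 RPTM (ratio 36.1, 12.0 to 178).

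The Dicer gene itself, the target of the knockdown, held the most abundant gain in both size classes. Where the reads assigned to this gene came from was not tested, so the gain cannot be read as a change at the gene's own locus. In a window of LOC_Os10g34430 on chromosome 10, from 18367000 to 18367499, 24-nt siRNA rose from 4.98 to 7417 RPTM, or 4 to 5458 reads (ratio 1489, 582 to 5472). In the same window 21-nt siRNA rose from 6.22 to 17550 RPTM, or 5 to 12914 reads (ratio 2822, 1209 to 8690). The 21-nt reads of this window made up 0.176% of the knockdown library (exact 95% interval 0.172% to 0.179%) and the 24-nt reads 0.0742% (0.0722% to 0.0762%), a 21-nt to 24-nt ratio of 2.37. It was the 1 window of the lists that was shared by both size classes.

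Among 21-nt siRNA windows, 10 of 11 were lower in the knockdown, and the window in the Dicer gene was the 1 that was higher. The lower windows lay in 2 places. On chromosome 6, 7 of them and 3 lower 24-nt windows lay between 24642000 and 24701499, a stretch of 59.5 kb, with 2506 wild type reads and 3 knockdown reads in all. The largest, an intergenic window from 24676500 to 24676999, went from 1379 to 1.36 RPTM of 21-nt siRNA. The 21-nt windows in LOC_Os06g41240 and LOC_Os06g41210 went from 269 and 221 RPTM to no read. Against a floor of 3 reads, or 4.08 RPTM, in the knockdown library these were 65.9-fold and 54.3-fold lower. Their exact intervals start lower, at 53.2 and 43.7. On chromosome 8, 3 adjoining windows in the pectinesterase gene LOC_Os08g12410, from 7325000 to 7326499, fell, with the most abundant at 434 against 59.8 RPTM (ratio 7.26, 5.30 to 10.2).

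The small RNA values come from 1 library per genotype with no replicate check, so the intervals compare these libraries, not the genotypes, and cover counting error only.

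**Figure D4:**
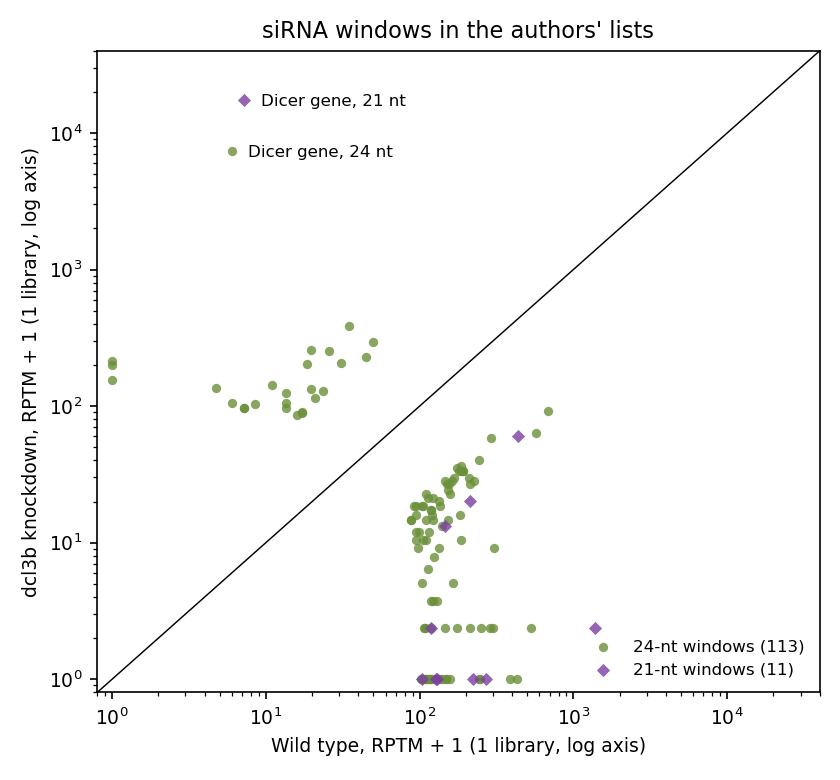
RPTM of each listed siRNA window in the wild type library (x axis) and the knockdown library (y axis), on log axes after adding 1; circles are 24-nt and diamonds 21-nt windows, and the line marks equal levels. The window in the Dicer gene reaches 17550 RPTM of 21-nt and 7417 RPTM of 24-nt siRNA in the knockdown, and most other windows lie below the line.

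The last comparison asked whether changed transcripts and changed siRNA windows fell on the same genes. The 24-nt windows named 113 loci, of which 7 were among the changed genes, 4 that rose and 3 that fell (Fisher's exact test of higher against lower, two-sided, p = 1). In 5 of the 7 genes siRNA and transcript moved the same way, or in 5 of 6 without the Dicer gene, the target of the knockdown. LOC_Os03g14040, without a functional description, rose from 8.51 ± 1.01 to 68.9 ± 3.34 FPKM (SD, n = 3) while its 24-nt siRNA went from 19.9 to 113 RPTM. The ferredoxin-nitrite reductase gene LOC_Os02g52730 rose from 0.110 ± 0.0300 to 0.673 ± 0.312 FPKM with siRNA at 7.46 and 102 RPTM. LOC_Os06g03650 was listed at 0 FPKM in wild type and at 0.923 ± 0.624 FPKM in the knockdown, with siRNA at 33.6 and 383 RPTM. The ankyrin gene LOC_Os02g29130 fell from 0.273 ± 0.0902 to 0.0233 ± 0.00577 FPKM with siRNA at 157 and 21.7 RPTM, and LOC_Os08g38760 from 0.0733 ± 0.0208 to 0.02 ± 0.01 FPKM with siRNA at 97.0 and 8.15 RPTM. Opposite changes were seen in the Dicer gene and in the beta-glucosidase gene LOC_Os03g53790, which rose from 3.99 ± 1.74 to 10.2 ± 4.81 FPKM with siRNA at 190.4 and 32.6 RPTM. Genes were matched to windows by the locus IDs in the authors' tables, since no gene coordinates on the build of the windows were used here.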

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

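The limma re-test itself, the gene lists over the genes past it, with all libraries and with each left out, the separation counts with each library left out, the lists without genes listed at 0 in wild type and the match of genes to windows by locus ID were chosen after the data were seen. With an absolute log2 fold change of at least 2, 396 genes that rose and 90 that fell remained of 644 and 530, and 2 lists passed in place of 8: the anther, MYB and histone lists had no member left and so no value, and the cell wall, NAC and heat shock protein lists had under 5. With an adjusted p of at most 0.01, 328 genes that fell were left and 4 lists passed, without the MYB, NAC, F-box and histone lists, and without genes listed at 0 in wild type 4 lists passed, without the cell wall, MYB, NAC and histone lists; fewer genes enter each of these. Over the genes past the limma re-test with all libraries 8 lists passed, the lipid transfer and auxin lists in place of the MYB and histone lists; against these, leaving out each library in turn gave 5 to 8 lists. It gave 412 to 608 higher and 352 to 501 lower genes in the re-test, against 580 and 513 with all libraries, and the pseudocounts moved neither count by over 1.5 times. Over the 20 tested lists under the stricter limits, without genes listed at 0 and over the genes past the re-test, 55 of 77 values came from lists with enough members for the test: 48 stayed on their side of the threshold, 5 lost it and 2 gained it. The other 22 were not tested, 8 of them of lists called with all genes. Over the 16 lists tested among the genes past the re-test, with each library left out, 87 of 96 were tested: 77 stayed, 9 lost it and 1 gained it. Of the 9 not tested, 5 were of called lists. The sign of the difference in shares changed in 11 values of 10 lists, of which 3 were tested and short of the threshold and 8 had too few members for the test, and, with a library left out, in 1 tested value short of it. Raising the ratio limit to 10.1, double the smallest listed, left 14 higher and 47 lower 24-nt windows of 26 and 87, and the top 75% by value held 17 higher ones. The 21-nt window counts and the window shared by both size classes kept their values within 1.5 times. At the doubled 21-nt limit of 14.5, however, the pectinesterase windows of chromosome 8 (ratios 7.26, 11.1 and 11.9) dropped out. The lower 21-nt windows left were the 7 of chromosome 6.

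With the replicate number as a block the re-test gave 471 higher and 408 lower genes. The numbers did not pair the libraries: deviations from the group means correlated at -0.0435, -0.530 and -0.427 between libraries of the same number. No library correlated best with its own number. Distances of 1 and 5 kb between genes and windows were not run, for lack of gene coordinates on the build of the windows, and neither were DESeq2 and other scalings, which need counts of all genes. The depth of the mRNA libraries is unknown, and a count of 0 in a small RNA window was set against a floor of 3 reads.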

Other observations

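The tests of this part were chosen after the results were seen, apart from the count of genes under other splits of the libraries.

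Further groups were picked from the descriptions after the data were seen. Exact tests run on their counts are void for that reason, and no p is given here. All 7 listed ribosome-inactivating protein genes fell, with a median log2 fold change of -1.43 in the authors' deposited table. All 5 listed cyclin genes fell, with a median of -2.02 in the authors' deposited table, as did 3 SMP-30 family genes. Of GDSL lipase genes 6 rose and 2 fell, of transmembrane amino acid transporter genes 3 rose and 4 fell, and of defensin genes 3 rose and 1 fell. All 3 listed terpene synthase genes rose.

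Some transcripts that were almost absent from wild type were abundant in all 3 knockdown libraries; these examples were chosen after their values were seen. LOC_Os03g02470, without a functional description, was listed at 0, 0.02 and 0 FPKM in wild type and at 110.4, 117 and 113 FPKM in the knockdown. LOC_Os11g34824, also undescribed, was at 0.04, 0.02 and 0 FPKM in wild type and at 37.2, 30.9 and 25.4 FPKM in the knockdown. LOC_Os07g02430 was at 0, 0.03 and 0 FPKM against an uneven 14.2, 88.5 and 38.7 FPKM. The retrotransposon gene LOC_Os06g43150 was at 0.01 FPKM in each wild type library and at 13.2, 10.3 and 12.8 FPKM in the knockdown.

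The 11 fallen anther genes and the 9 genes listed as higher, 3 of pollen and anther proteins and 6 of lipid transfer proteins, went apart by library: the mean log2(FPKM + 0.5) of the 9 was 3.55, 4.03 and 2.43 in wild type replicates 1 to 3 and 5.41, 3.84 and 5.52 in the knockdown, and that of the 11 was 6.25, 6.27 and 6.27 against 4.39, 5.51 and 4.76. A candidate explanation is that the libraries came from panicles of slightly different stage. The difference of wild type replicate 2 minus 3 and that of knockdown replicate 3 minus 2, which share no library, had a Spearman's rho of 0.191 over the 11 fallen genes, which does not decide the point; genes are not independent replicates. Over other sets rho was 0.833 (the 9 genes), 0.449 (all 1174 listed genes), 0.554 and 0.212 (genes outside transposons that rose and that fell), 0.121 (transposon genes), -0.117 (the 9 heat shock genes) and -0.714 (the 6 histone genes). Between those wild type libraries the 11 genes differed by a median log2 of 0.08 and the 9 by 1.31, against -0.60 and 1.47 between the knockdown libraries. In each genotype these were the highest and the lowest library by the mean of the 9 genes. Positive medians of the 9 thus follow from the choice of libraries. Whether stage accounts for the whole fall stays open: in knockdown replicate 2, whose mean of the 9 genes lay inside the wild type range, 11 of 11 fallen anther genes were still below all 3 wild type libraries, but this is 1 library. An effect of the knockdown on the anther, which the design would give, is untested apart from stage.

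Of the 133 genes listed at 0 in every wild type library and called higher, 58 were transposon genes and 55 had no functional description, with a median of 0.36 FPKM in the knockdown. Knockdown replicate 3 over 2 had a median log2 ratio of 0 over 131 of these genes, where the 9 higher genes had 1.49. The 95% bootstrap interval over genes was -0.0641 to 0.138. The difference between these libraries that moves the 9 genes was thus not seen in this set as a whole. That does not settle the source of the set: both sets were selected on these values, and the ratio rests on a single pair of libraries. The 9 genes are not shown to read stage, so a difference of stage stays open. A few chromosome segments from another parent may also give such genes. Of the 133, 19 had a neighbour from the set within 100 locus numbers, against a median of 12 in 10000 random sets of the genes that rose (4 to 21 in 95% of sets, one-sided permutation p = 0.0699), so that explanation stays open, as do loss of silencing in the knockdown and sequence differences of the knockdown line. The listed windows do not tie the transposon genes to a loss of siRNA. The 7 changed genes named by 24-nt windows had descriptions other than transposon. Among those 7, LOC_Os06g03650, listed at 0 in wild type, gained 24-nt siRNA, from 33.6 to 383 RPTM.

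The stretch of chromosome 6 with 2506 wild type siRNA reads had at most 1 knockdown read in any listed window, for 21-nt and 24-nt siRNA alike. A segment missing from the genome of the knockdown line may give this, and so may a loss of the siRNA precursor's transcription; a maximum of 1 read per window cannot separate them, and none of the loci named in these windows was among the changed genes (0 listed). No test here bears on whether the Dicer-like gene acts on this stretch.

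The re-test of the listed genes called 1093 genes between the genotypes, and the highest of the other splits of the 6 libraries into 3 and 3 called 0. The real split was the 1 of 10 with as many genes. With 10 splits the share cannot go below 0.1, and the genes were selected on the real split.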
